A study of Mus musculus with 2 samples.

How the data were processed

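H3K4me2, the di-methylated form of lysine 4 on histone H3 that marks promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in forebrain of mouse embryos at embryonic day 16.5. The set held 1 group of 2 biological replicates of the C57BL/6NCrl strain, each a pool of embryos of mixed sex. Per the labels, replicate 2 pooled 41 embryos, and the number pooled for replicate 1 was not given. With 1 group there was no comparison between conditions, and every comparison was made within the group: between the replicates, between parts of the genome, or between gene lists.

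The authors deposited 4 peak lists in narrowPeak format on the mm10 build: a list for each replicate, a list called on both replicates pooled, and a replicated list derived from the other 3. The aligner, the peak caller, their versions and the rule that made the replicated list were not given in the sources used here. The deposited lists give each peak a signal value, in a unit the authors did not define, so signal values were compared as ranks, ratios or correlations and read within a list. An exception, described below, paired peaks of like signal value across the lists of the 2 replicates. The deposited lists also give the caller's −log10 p, not adjusted, and its −log10 q for each peak. The smallest −log10 p was 2.00 in each replicate's list, and 2.87% of the peaks of replicate 1 and 5.59% of those of replicate 2 had a q above 0.05. Replicate 1's list and the pooled list each name 1 more parent file than the list of replicate 2, with no role stated. The lists hold no read counts, so the depth of each library is unknown here, and no counting interval or detection floor was given. The error given with a value is the SD of the 2 replicates, computed from each replicate's own list.

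All 39954 replicated peaks on the assembled chromosomes were also in the pooled list with the same ends and signal value. Of the replicated peaks, 97.0% touched a peak of replicate 1's own list and 90.0% touched a peak of replicate 2's own list, so the replicated list holds peaks that were not called in both replicates alone. An alternative kept only the replicated peaks that touched both.

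Genes and start sites were taken from GENCODE M21 on GRCm38, the same build as mm10. The main analysis used 21853 protein-coding genes on the 19 autosomes, X and Y, with 54361 annotated protein-coding start sites. A gene counted as marked when a replicated peak lay within 1 kb of any of its starts. Peaks were placed by their midpoint as promoter (within 1 kb of a start), exon, intron or intergenic. Chance levels for overlap and location came from 100 random placements of the peaks on the same chromosomes, outside assembly gaps of 1000 bp or more. The CpG observed/expected ratio was taken from 500 bp either side of each start. A gene's CpG ratio was the highest among its starts, which need not be the start used for breadth below.

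The breadth of H3K4me2 at a gene was the number of bases covered by a replicate's own peaks within 5 kb either side of the start with the most coverage, averaged over the replicates. The window of 10001 bases sets the largest breadth that can be read. Every peak in the window counted, including any at the start of a neighbouring gene. Distal peaks were replicated peaks over 1 kb from every protein-coding start. Each was assigned to the gene with the nearest start if that lay within 100 kb. A gene's territory was the stretch from which such a peak would be assigned to it.

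The 25 gene lists were fixed before the data were examined, as were the tests, the rule for naming genes and the first set of alternatives. They were pan-neuronal, neural progenitor and radial glia, neurogenic and intermediate progenitor, deep-layer cortical neuron, upper-layer cortical neuron, GABAergic and ventral telencephalon, forebrain patterning, synaptic and activity-regulated, oligodendrocyte lineage, astrocyte, microglia and myeloid, endothelium and pericyte, choroid plexus and meninges, erythroid, hindbrain and spinal cord transcription factors, Hox clusters, liver, heart and skeletal muscle, gut with pancreas and kidney, limb with bone and epidermis, germline, housekeeping, H3K4 methylation and Polycomb enzymes, cell cycle, and olfactory receptors. The first 8 are called the neural lists. The 24 lists fixed by symbol held 433 entries, and the olfactory receptor list took 1133 genes by symbol.

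The share of marked genes in a list was compared with all other protein-coding genes by Fisher's exact test, two-sided. The share and the median breadth of each list were then set against 10000 random lists of the same size, matched on CpG ratio in 10 bins, and the median number of distal peaks against 10000 lists matched on territory length in 10 bins. These gave two-sided permutation p values, of which 0.0002 is the smallest that 10000 random lists can give. All list p values were adjusted by the Benjamini-Hochberg method over the 25 lists, with a threshold of 0.05. Genes and peaks are not independent replicates, so these p values describe these peak lists and not a population of embryos. Random lists were drawn gene by gene, with no allowance for clustered neighbours that share peaks, as Hoxd3 and Hoxd4 do.

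The 12 sequence words were counted on both strands in 400 bp round the midpoint of each distal peak and in flanking windows of 400 bp at 5 kb to either side that touched no peak of any list. Pairs were compared by an exact McNemar test, two-sided, adjusted over the 12 words. Of the distal peaks, 20765 had a flank to compare and 395 did not. Each word read backwards without complementing served as a control of base composition.

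Named genes were chosen by rule: in each list the 2 members with the largest breadth and up to 2 unmarked members in alphabetical order, the 15 genes with the largest breadth, the 15 with the most distal peaks, and 2 top members of each list past the distal threshold. A member at either end of a list past the threshold could also be named. Named peaks were the 5 widest replicated peaks, the 5 distal peaks with the largest signal value, and the 3 of largest signal value in each replicate that touched no peak of the other.

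The methods were tested on simulated data. Simulated lists of 18 genes were called at an unadjusted p of 0.05 in 2% of 100 sets with no added breadth, 25% with 500 bp added, 77% with 1000 bp and 100% with 2000 bp. For marked shares, 1% were called with no marks removed and 99% with 50% kept. For distal peaks, 0% were called with unchanged counts, 75% with 3 times and 99% with 5 times the count. These counts were Poisson draws in proportion to territory. Real counts were not shown to follow that form, so the rates need not hold for them. With the windows of each pair swapped at random, 0 of 12 words were called.

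Alternatives were each replicate's own list in place of the replicated list, the pooled list, only peaks at or above the median signal value, other windows and distances (500 bp, 2 kb, 5 kb, 10 kb, 50 kb, 200 kb), the gene's 5' end alone, random lists without matching, only marked genes, an overlap of 50%, −log10 p in place of signal value, covered bases in place of midpoints, and motif windows of 200 bp. Peaks on unlocalized and unplaced scaffolds were left out of gene and region analyses, because the start sites were taken on assembled chromosomes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.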

Results

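Peaks of H3K4me2 were listed for embryonic mouse forebrain at day 16.5, a stage at which the cortex adds upper-layer neurons and glial production begins. The 2 biological replicates formed 1 group, so the data addressed which genes and regions carried the mark and how closely the replicates matched. Replicate 1 had 49980 peaks and replicate 2 had 42268, a mean of 46124 ± 5453 (SD, n = 2). They covered 44.0 ± 4.35 Mb of the genome (SD, n = 2), with a median width of 653 ± 63.3 bp (SD, n = 2). The pooled list had 42876 peaks over 46.2 Mb and the replicated list 39968 over 45.5 Mb, with a median width of 832 bp. Sequencing depth was not given and is unknown.

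The widest replicated peak, 23066 bp at chromosome 3, 88199216 to 88222281, covered the microRNA gene Mir9-1, which acts in neural progenitors, inside the non-coding gene Gm3764. The fifth widest, 17390 bp at chromosome 7, 79495898 to 79513287, covered its paralog Mir9-3. The other 3 were 20963 bp at chromosome 5, 111414422 to 111435384, over Mn1, a transcriptional regulator; 18257 bp at chromosome 2, 116055042 to 116073298, over the start of the homeobox gene Meis2; and 17508 bp at chromosome 12, 107989296 to 108006803, over Bcl11b, a zinc finger gene of subcerebral projection neurons. The distal peak with the largest signal value, 55.7 in the pooled call, lay between genes at chromosome 5, 52112122 to 52116835, and was 4714 bp wide. The next were 54.4 in the non-coding gene C130073E24Rik (chromosome 8, 50914708 to 50917528), 52.5 in an intron of Phactr1 (chromosome 13, 42915870 to 42918308), 52.0 over an exon of Cdh23 (chromosome 10, 60686072 to 60688020) and 51.7 over the histone gene Hist1h1d (chromosome 13, 23554312 to 23556780).

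The replicates shared most of the covered genome, and the peaks found in only 1 of them were short and weak. Of replicate 1's peaks, 73.9% touched a peak of replicate 2, and 93.2% of replicate 2's peaks touched a peak of replicate 1. Random placement gave 3.26 ± 0.0949% of replicate 1's peaks (SD over 100 placements). Both covered the same 38.7 Mb, a Jaccard index of 0.785 against 0.00916 by chance. Replicate 1 had 13025 peaks that touched none of replicate 2, with a median signal value of 3.24 against 12.8 for its shared peaks and a median width of 236 bp against 902 bp. Replicate 2 had 2897 such peaks, with a median signal value of 3.36 against 10.7. The largest signal value among the unshared peaks was 7.62 in replicate 1, and the 3 peaks named by rule had this value: in an intron of 0610010F05Rik (chromosome 11, 23632051 to 23632366), between genes (chromosome 11, 110800314 to 110800737) and in an intron of Erbin (chromosome 13, 103917967 to 103918217). In replicate 2 the largest were 6.96, 6.77 and 6.32, all between genes, with Batf, Adgrl2 and Prkab1 as the nearest coding genes. Across 35311 overlapping pairs of peaks, signal values had a Pearson correlation of 0.939 on the log2 scale and a Spearman correlation of 0.929. These are correlations across peaks, which are not independent replicates, and Spearman values by chromosome ranged from 0.874 to 0.935.

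Most protein-coding genes carried H3K4me2 at a start, and the CpG content of their starts separated those that did from those that did not. A replicated peak lay within 1 kb of a start in 14327 of 21853 genes, or 65.6%. The replicates' own lists marked 14353 ± 89.1 genes (SD, n = 2), with 14243 marked in both, 173 in replicate 1 alone and 47 in replicate 2 alone. The share of marked genes was 1.1 ± 0.13% (SD, n = 2) in the lowest decile of genes by CpG ratio, 15.4 ± 1.39% (SD, n = 2) in the third, 53.9 ± 1.2% (SD, n = 2) in the fourth and 90.4 ± 0.65% (SD, n = 2) in the fifth. In the top decile it was 99.6% in each replicate.

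**Figure D1:**
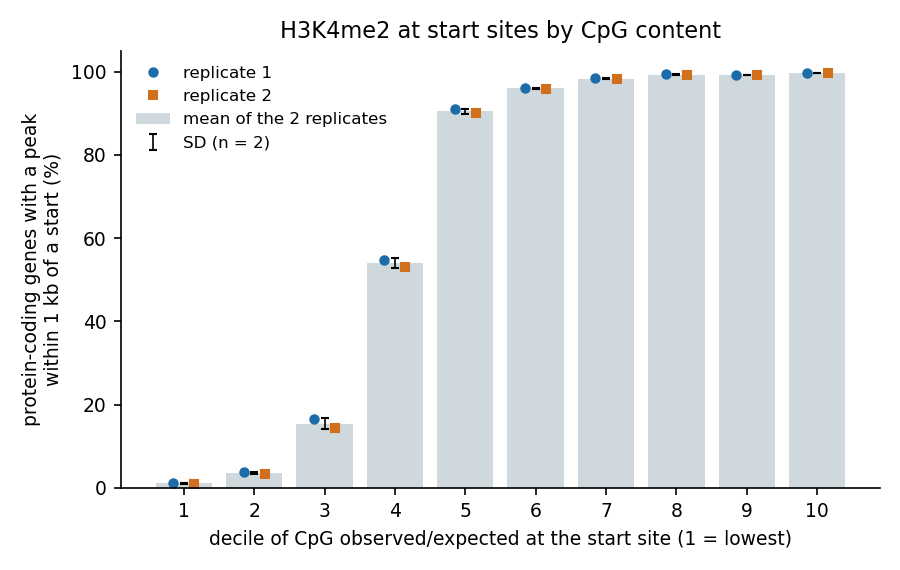
Share of protein-coding genes with a peak within 1 kb of a start (vertical axis, percent) by decile of CpG observed/expected ratio (horizontal axis). The ratio is the highest among a gene's starts. Bars show the mean of the 2 replicates, error bars the SD (n = 2) and points each replicate. The share was 15.4% in the third decile and 90.4% in the fifth.

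Promoter peaks were wider and stronger at the median than exon, intron or intergenic peaks. Promoter midpoints made up 42.2% of replicated peaks, against 2.64 ± 0.082% in random placements (SD over 100 placements), a ratio of 16.0. In the replicates' own lists the promoter share was 39.6 ± 5.25% (SD, n = 2). Exons held 5.06% against 3.26% by chance, introns 26.4% against 36.1% and intergenic sequence 26.4% against 58.0%. Promoter peaks had a median width of 1340 bp and a median signal value of 23.5, and intron peaks 507 bp and 4.72. Among peaks at or above the median signal value the promoter share was 71.6%, over 1.5 times that of the full list.

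Every member of the 8 neural lists carried H3K4me2 at a start in the replicated list, while most members of the liver, muscle, gut with pancreas and kidney, germline, erythroid, myeloid and olfactory receptor lists were unmarked. The neural lists held the pan-neuronal genes (17 of 17), progenitor and radial glia genes (17 of 17), neurogenic genes (11 of 11), deep-layer (12 of 12) and upper-layer (10 of 10) cortical genes, GABAergic and ventral genes (23 of 23), forebrain patterning genes (19 of 19, with 18 in replicate 2's own list) and synaptic genes (23 of 23). The housekeeping genes (18 of 18), the H3K4 methylation and Polycomb enzymes (21 of 21) and the cell cycle genes (15 of 15) were also all marked. These 11 lists were above the 65.5% or so of other genes by Fisher's exact test, two-sided, with adjusted p from 0.00041 to 0.027.

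Below the other genes by the same test were 8 lists. They were olfactory receptors (3 of 1133), liver (1 of 18), germline (2 of 16), microglia and myeloid (4 of 18), erythroid (4 of 15), gut with pancreas and kidney (4 of 15), heart and skeletal muscle (8 of 24) and Hox clusters (15 of 39). In the replicates' own lists more Hox genes were marked, 20 in replicate 1 and 16 in replicate 2. Unmarked members included Afp, which encodes the fetal serum protein alpha-fetoprotein, and Ahsg, which encodes fetuin A, both made in liver. They also included Acta1 and Actc1, skeletal and cardiac actin; Cdx1 and Cdx2, homeobox regulators of the gut; Ddx4 and Figla, regulators of germ cells; Alas2 and Epb42, which act in red cells; Aif1 and C1qa, markers of microglia; and the odour receptors Olfr1 and Olfr10. Unmarked within 1 kb of a start but with peaks further out were Tnp2 of germline, with 2793 ± 229 bp within 5 kb, Apoa2 and Apoa1 of liver, with 1966.5 ± 46.0 bp and 1339 ± 161 bp, and Acta1, with 1924 ± 43.8 bp (SD, n = 2). The marked members of the lists with 4 or fewer, named after their values were seen, were Trf, the transferrin gene, of liver, Dazl and Tex14 of germline, Hexb, Irf8, P2ry12 and Runx1 of the myeloid list, Gypa, Klf1, Nfe2 and Tal1 of the erythroid list, Nphs1, Nphs2, Six2 and Wt1 of gut, pancreas and kidney, and Olfr94, Olfr658 and Olfr1033.

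The remaining 6 lists were not separated from other genes by Fisher's exact test. By that exact test they were oligodendrocyte lineage (9 of 16, adjusted p = 0.50), astrocyte (12 of 15, adjusted p = 0.34), endothelium and pericyte (15 of 20, adjusted p = 0.50), choroid plexus and meninges (9 of 13, adjusted p = 1), hindbrain and spinal cord factors (16 of 20, adjusted p = 0.30) and limb with bone and epidermis (10 of 18, adjusted p = 0.50). Among their unmarked members were Gpr17 and Mag of the oligodendrocyte list, Aqp4 and Gfap of astrocytes, Cdh5 and Emcn of endothelium, Folr1 and Kcnj13 of choroid plexus, Evx1 and Evx2 of the spinal cord, and Bglap and Ivl of bone and epidermis.

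Against random lists matched on CpG ratio, fewer lists stood apart. The neurogenic genes were above, at 100% against a matched median of 72.7% (permutation, two-sided, adjusted p = 0.0025). The Hox clusters were below, at 38.5% against 92.3%, and olfactory receptors were below, at 0.265% against 7.06% (permutation, adjusted p = 0.0017 for each, from 0.0002, the smallest that 10000 random lists can give). Germline genes were also below with adjusted p = 0.0017, and the genes of gut, pancreas and kidney were below at 26.7% against 53.3% (permutation, adjusted p = 0.005). The other 20 lists did not pass. The matched median was itself 100% for the upper-layer, GABAergic and ventral, forebrain patterning, housekeeping, enzyme and cell cycle lists. None of them could therefore be above. The pan-neuronal, progenitor, deep-layer and synaptic lists were also at 100%, so their shares could not have been placed higher. The erythroid list, below other genes by Fisher's exact test, lay above its matched median, at 26.7% against 13.3% (permutation, adjusted p = 0.51). Some of the 20 passed in alternatives. The astrocyte list (permutation, adjusted p = 0.11) was above with replicate 1's own list (0.027), with a window of 2 kb (0.039) and with the 5' end alone (0.016), and the pan-neuronal and synaptic lists were above in 2 alternatives each that kept the matching (0.005 to 0.045). Below were the hindbrain and spinal cord factors in 3 (0.00083 to 0.0067) and heart and skeletal muscle in 2 (0.00083 and 0.0064).

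Genes of the 8 neural lists carried broader H3K4me2 around their starts than matched genes, as tested list by list. By coverage within 5 kb of the start, Islr2 (chromosome 9, 58196297 to 58204319), a membrane protein of growing axons, ranked first among protein-coding genes. Its window of 10001 bp was covered in full in both replicates. Next were Meis2, with 9950.5 ± 7.78 bp, Lhx2, a LIM homeobox gene needed for cortical identity (chromosome 2, 38339281 to 38369733), with 9917 ± 119 bp, Bcl11a, a zinc finger gene of cortical neurons (chromosome 11, 24078056 to 24174123), with 9912 ± 126 bp, and Basp1, a growth cone protein, with 9866.5 ± 124 bp (SD, n = 2 for each). The other 10 of the first 15 ranged from 9494 bp at Otx1 to 9817 bp at Tcf4. They included Pax6, the paired-box gene of radial glia (chromosome 2, 105668900 to 105697364; 9742.5 ± 175 bp), Dlx1, a homeobox gene of ventral interneurons (chromosome 2, 71528113 to 71533981; 9659 ± 2.83 bp), Zeb2, Prdm16, Nrn1, the histone demethylase gene Kdm6b, Bahcc1 and Tnrc18 (SD, n = 2). The window caps breadth, so genes near 10001 bp are not ranked by their full extent. Within 10 kb either side, Islr2 had 12488.5 bp, below Meis2 at 19869.5 bp, Lhx2 at 18823.5 bp and Bcl11a at 17276 bp. Pou3f3, outside the first 15 by the 5 kb measure, had 19234.5 bp. Marked genes had a median breadth of 2181.5 bp, and 78 genes exceeded 8 kb. Across the 14327 marked genes, which are not independent replicates, breadth in the replicates had a Pearson correlation of 0.981.

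All 8 neural lists were broader than random lists matched on CpG ratio, with medians 2.22 to 2.92 times the matched median (permutation, two-sided, adjusted p = 0.0005 for each). The underlying p of 0.0002 is the smallest that 10000 random lists can give. The median was 6678 bp for forebrain patterning, against 2287 bp in matched lists, with Lhx2 and Otx1 as its broadest members within 5 kb. Within 10 kb either side, Nr2f1 at 18255.5 bp and Nr2f2 at 16874 bp exceeded Otx1 at 15461 bp. Upper-layer genes had a median of 6154 bp, with the POU genes Pou3f3 at 9430.5 ± 322 bp and Pou3f2 at 8629.5 ± 67.2 bp. GABAergic and ventral genes had 6091 bp, with Meis2 and Dlx1. Deep-layer genes had 5727.8 bp, with the signalling gene Wnt7b at 8537.5 ± 481 bp and Bcl11b at 8340.5 ± 14.8 bp (SD, n = 2). Progenitor genes had 5584.5 bp, with Pax6 and the stem cell factor Sox2 at 8868 ± 512 bp. Pan-neuronal genes had 4919.5 bp, with the RNA-binding gene Celf4 at 7595.5 ± 224 bp and the neuronal tubulin Tubb3 at 6934.5 ± 226 bp. Neurogenic genes had 4903.5 bp, with Insm1 at 8714 ± 471 bp and Neurod1 at 5533 ± 419 bp, and synaptic genes had 4210 bp, with the NMDA receptor subunit gene Grin2b at 7025.5 ± 41.7 bp and the scaffold gene Dlg4 at 6591.5 ± 264 bp (SD, n = 2). The SD of the replicates' medians ranged from 19.1 bp for neurogenic genes to 581 bp for progenitor genes, smaller than each list's distance from its matched median.

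Broader than matched lists were also the housekeeping genes, at 3519.5 bp against 2261.4 bp (permutation, adjusted p = 0.0025), with Polr2a and Ubc, and the astrocyte genes, at 3186 bp against 1340.8 bp (permutation, adjusted p = 0.00091). The broadest astrocyte members were the nuclear factor genes Nfib at 9165 ± 184 bp and Nfia at 8779 ± 191 bp (SD, n = 2), which are also expressed in progenitors and neurons, while Aqp4, the water channel of mature astrocytes, was listed at 0. The astrocyte call was lost with peaks at or above the median signal value (difference 401 bp; permutation, adjusted p = 0.52) and with the gene's 5' end alone (798.8 bp; permutation, adjusted p = 0.19).

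Narrower than matched lists were genes that pattern the body behind the forebrain, and germline genes. The Hox genes had a median of 319 bp against 2083 bp (permutation, adjusted p = 0.0005). Their broadest members were Hoxa7 at 1147.5 ± 89.8 bp and Hoxd8 at 1075.5 ± 68.6 bp (SD, n = 2), and Hoxa11 was listed at 0. Hindbrain and spinal cord factors had 1352 bp against 2152.5 bp (permutation, adjusted p = 0.0005), from 4177 ± 9.90 bp at Egr2 and 2629.5 ± 195.9 bp at En2 to 455 ± 17.0 bp at Evx1 (SD, n = 2). Germline genes had 0 bp against 1369 bp (permutation, adjusted p = 0.0065). The hindbrain call was lost without CpG matching (permutation, adjusted p = 0.60), where the difference was -256.2 bp. The germline call was lost with peaks at or above the median signal value (permutation, adjusted p = 0.055) and without CpG matching (permutation, adjusted p = 0.084), with differences of -1246 and -1592.9 bp.

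The other 12 lists were not separated from matched lists in breadth. Their medians were 2907.5 bp for cell cycle genes, where Ccnd2 reached 8045 ± 67.9 bp, 2840.5 bp for the H3K4 methylation and Polycomb enzymes, where Setd1b reached 8501.5 ± 299 bp, and 1651.8 bp for endothelium and pericyte genes, where Slc2a1 reached 3815.5 ± 665 bp (SD, n = 2). They were 1109 bp for choroid plexus and meninges, where Crabp2 was broadest, 868.8 bp for limb with bone and epidermis, where Prrx1 and Col2a1 were broadest, and 683.8 bp for the oligodendrocyte lineage. In that last list Sox8 had 5868.5 ± 169 bp and Olig2 5656.5 ± 1309 bp (SD, n = 2). The median was 108.8 bp for heart and skeletal muscle and 0 bp for microglia and myeloid, erythroid, liver, gut with pancreas and kidney, and olfactory receptor genes. For the myeloid, erythroid, liver and olfactory receptor lists the matched median was also 0 bp, so none of them could be called narrower there. With only marked genes, the myeloid, muscle, gut with pancreas and kidney, and olfactory receptor lists were narrower (permutation, adjusted p = 0.025, 0.0033, 0.0076 and 0.043). These calls rest on only 4, 8, 4 and 3 marked genes. Without CpG matching, the enzyme and cell cycle lists were broader (permutation, adjusted p = 0.0042 and 0.0065) and the olfactory receptors narrower (0.0005).

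Peak coverage also differed between whole loci chosen for display. In a window of 100 kb round Dlx1 and Dlx2, peaks covered 22.9 ± 1.55 kb (SD, n = 2), and in a window of the same size over the Hoxd cluster, which sets posterior identity, 4.09 ± 0.368 kb (SD, n = 2). In a window of that size round Mir9-1 they covered 31.4 ± 1.22 kb (SD, n = 2). These differences were larger than the spread between replicates, and the windows were chosen for display, so no test was made. They do not stand for forebrain and posterior genes as groups. In distal peaks, hindbrain and spinal cord factors had a median of 2 against 0.5 in matched lists (permutation, adjusted p = 0.060). The Hox genes had 0 against 0, so a test on medians could not place them below.

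**Figure D2:**
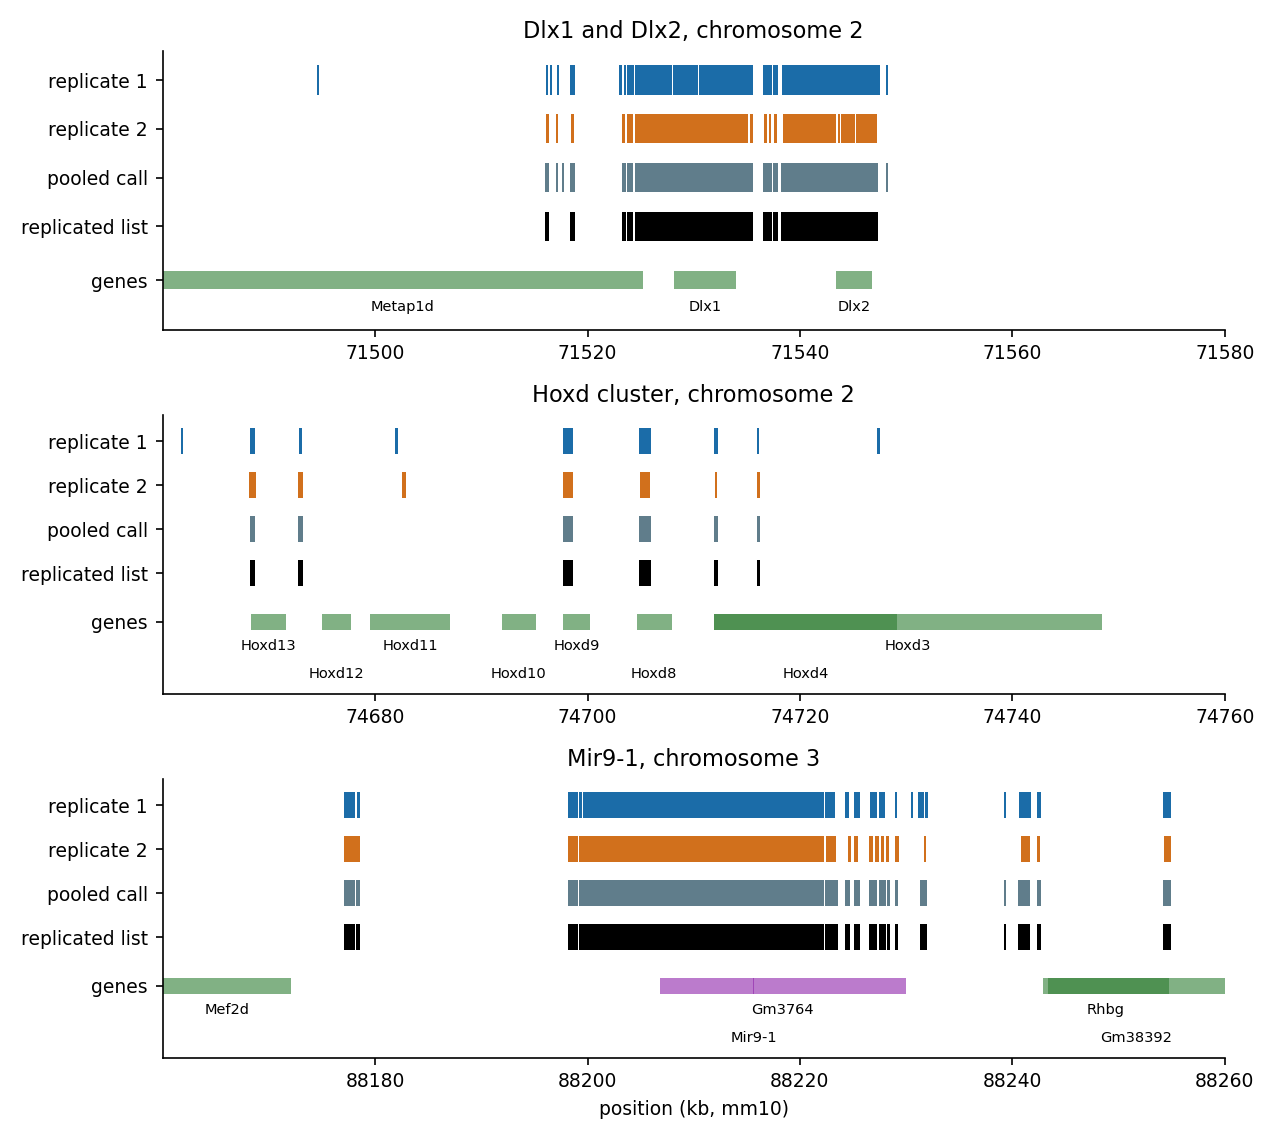
Peaks of each replicate, the pooled call and the replicated list over 3 windows of 100 kb (horizontal axis, position in kb on mm10), with protein-coding genes in green. Of the non-coding genes only Gm3764 and Mir9-1 are drawn, in purple. Peaks covered 22.9 kb round Dlx1 and Dlx2, 4.09 kb over the Hoxd cluster and 31.4 kb round Mir9-1, as means of the 2 replicates.

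Away from promoters, Nfib, Foxp1 and Tcf4 had the most H3K4me2 peaks, and 7 gene lists had more than matched lists. There were 21160 distal replicated peaks, or 53.0% of those on chromosomes, and 16773 were assigned to 7474 genes. Nfib, a nuclear factor gene of radial glia and neurons (chromosome 4, 82290173 to 82705750), had the most, with 41 in the replicated list and 46.0 ± 8.49 in the replicates' own lists (SD, n = 2). Foxp1, a forkhead gene of striatal and cortical neurons (chromosome 6, 98925338 to 99522721), had 30 and 38.0 ± 12.7, and Tcf4, a partner of neuronal bHLH factors (chromosome 18, 69343356 to 69689079), had 29 and 42.5 ± 7.78 (SD, n = 2). Gse1 had 27, with 41 in replicate 1's own list, Zic4 and Zfhx3 had 22 each, and Mef2c, Nfix and Runx1t1 had 21 each. E130114P18Rik, whose start lies beside that of Nfia, had 22. Satb2, which specifies upper-layer neurons (chromosome 1, 56793981 to 56978650), and Chd2 had 20 each, Nr2f1 had 19, and Bcor and Gm11146 had 18 each.

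By list, 7 had more distal peaks per gene than random lists matched on territory. The medians of the replicated list were 6 for GABAergic and ventral genes (23 of 23 with a distal peak), 5 for progenitor genes (15 of 17), 5 for forebrain patterning (18 of 19) and 4 for neurogenic genes (10 of 11), against 0 to 1 in matched lists (permutation, two-sided, adjusted p = 0.0012 for each). Upper-layer genes had 5.5 (10 of 10; permutation, adjusted p = 0.002), pan-neuronal genes 3 (15 of 17; permutation, adjusted p = 0.022) and synaptic genes 2 (19 of 23; permutation, adjusted p = 0.047). Leading members besides those above were Sox2 with 15, Gli3, the Hedgehog pathway factor, with 12, Rbfox3 and the bHLH gene Neurod2 with 11 each (17 each in replicate 1's own list), Nr2f2 with 17, Eomes, a factor of intermediate progenitors, with 8, and the synaptic adhesion gene Nrxn3 with 9 (15 and 14 in the replicates' own lists). The synaptic call was lost in 8 of its 10 alternatives, among them each replicate's own list (1 and 2 above matched lists; permutation, adjusted p = 0.23 for replicate 1 and 0.055 for replicate 2), and the pan-neuronal and upper-layer calls were lost with peaks at or above the median signal value (differences of 0 and 1; permutation, adjusted p = 1 and 0.052), the pan-neuronal call also with assignment within 200 kb and with peaks over 5 kb from every start (permutation, adjusted p = 0.064 and 0.079), where the median was still 2 above that of matched lists. From replicate 1's own list the upper-layer median was 9, over 1.5 times that of the replicated list.

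The other 18 lists did not pass. Deep-layer genes had a median of 3, with a permutation adjusted p = 0.082, and their member Bcl11b had 15 (23 and 25 in the replicates' own lists), while hindbrain and spinal cord factors had a median of 2, with a permutation adjusted p = 0.060. The hindbrain list passed in all 10 alternatives, the deep-layer list in 7 and the oligodendrocyte list in 4 (permutation, adjusted p from 0.012 to 0.045). The astrocyte list, with a median of 1, had 3 in replicate 2's own list and passed with that list (permutation, adjusted p = 0.0014) and by the mean, 6.27 against 1.07 (permutation, adjusted p = 0.00083), which was chosen after seeing the data. The median was 1 for the oligodendrocyte lineage, astrocyte, heart and skeletal muscle, limb with bone and epidermis, enzyme and cell cycle lists and 0.5 for endothelium and pericyte. It was 0 for microglia and myeloid, choroid plexus and meninges, erythroid, Hox, liver, gut with pancreas and kidney, germline, housekeeping and olfactory receptor genes. Their matched medians were also 0, so the test on medians could not place any of these lists below.

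The X chromosome carried fewer peaks per Mb than the autosomes in both replicates. Its density was 8.05 ± 0.41 per Mb against 18.7 ± 2.25 per Mb on autosomes (SD, n = 2), and 51.3% of its genes were marked against 66.8%. In the replicated list X had 6.97 per Mb and autosomes 16.2, from 12.2 on chromosome 14 to 24.1 on chromosome 11. Chromosome Y had 8 replicated peaks. Each library pooled embryos of both sexes, so X copies per cell differed within a pool.

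Distal peaks held the word of the insulator protein CTCF several times as often as flanking sequence, and 5 other words more often by smaller ratios. The CTCF word CCASYAGRKGGC occurred in 1.92% of distal windows against 0.241% of flanks, a ratio of 7.98 (6.12 ± 0.00867 in the replicates' own lists, SD, n = 2). The E-box CAGCTG, bound by proneural factors such as ASCL1, had a ratio of 1.58 (1.51 ± 0.034, SD, n = 2), the octamer ATGCAAAT, bound by POU factors, 1.51 (1.57 ± 0.069, SD, n = 2) and the homeodomain word TAATTA 1.14 (1.13 ± 0.030, SD, n = 2). The nuclear factor I word TTGGCNNNNNGCCAA had 2.70 (2.95 ± 1.13, SD, n = 2), from only 27 peak windows and 10 flanks, and the MEF2 word CTAWWWATAG had 1.43 (1.55 ± 0.025, SD, n = 2). Lower than in flanks were CATATG, a neuronal bHLH E-box, with 0.598, AGATAAG, the GATA word of blood, with 0.726, and TGASTCA, the AP-1 word, with 0.863. Read backwards, CATATG had a ratio of 0.533 and TGASTCA 0.838, both at or below the word itself, so neither was lower than its control of base composition. AGATAAG read backwards had 0.883.

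By exact McNemar tests, two-sided, adjusted p was 4.2e-127 for CAGCTG, 3.0e-68 for the CTCF word, 2.0e-14 for the octamer, 2.3e-06 for TAATTA, 0.0042 for the MEF2 word and 0.010 for the nuclear factor I word. It was 5.3e-54 for CATATG, 1.1e-12 for AGATAAG and 0.00019 for TGASTCA. The E-box CAGATG, with a ratio of 1.02 and an exact test's adjusted p = 0.34, the SOX word CCATTGT, with 0.949 and 0.21, and the HNF1 word GTTAATNATTAA, with 0.462 and 0.20, did not pass; the last had ratios of 1 and 0.364 in the lists of replicates 1 and 2. Peaks were richer in G and C, at 50% against 44.4% in flanks. CAGCTG read backwards, which contains a CpG, had a ratio of 2.03, above that of the word itself. The octamer, the nuclear factor I word and the CTCF word read backwards also contain a CpG. Those reversals therefore do not control for base composition alone. CAGATG read backwards had 0.605, below the word itself. With peaks at or above the median signal value, a smaller set, CAGCTG and the CTCF word stayed past the threshold. The octamer at 1.32, the nuclear factor I word at 1.67 and the MEF2 word at 1.42 had ratios above 1 but no longer passed (exact test, adjusted p = 0.062, 0.73 and 0.32). In that set TAATTA turned to 0.868, CAGATG was lower at 0.819 (exact test, adjusted p = 1e-06) and CCATTGT was lower at 0.746 (exact test, adjusted p = 0.0063), while with the pooled list CAGATG was higher at 1.03 (exact test, adjusted p = 0.023). The MEF2 word was also lost with the replicated peaks that touched both replicates' peaks, at a ratio of 1.22 (exact test, adjusted p = 0.21). With windows of 200 bp the MEF2 word at 1.27, the nuclear factor I word at 2 and TAATTA at 1.07 stayed above 1. None of these passed there (exact test, adjusted p = 0.29, 0.29 and 0.13).

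**Figure D3:**
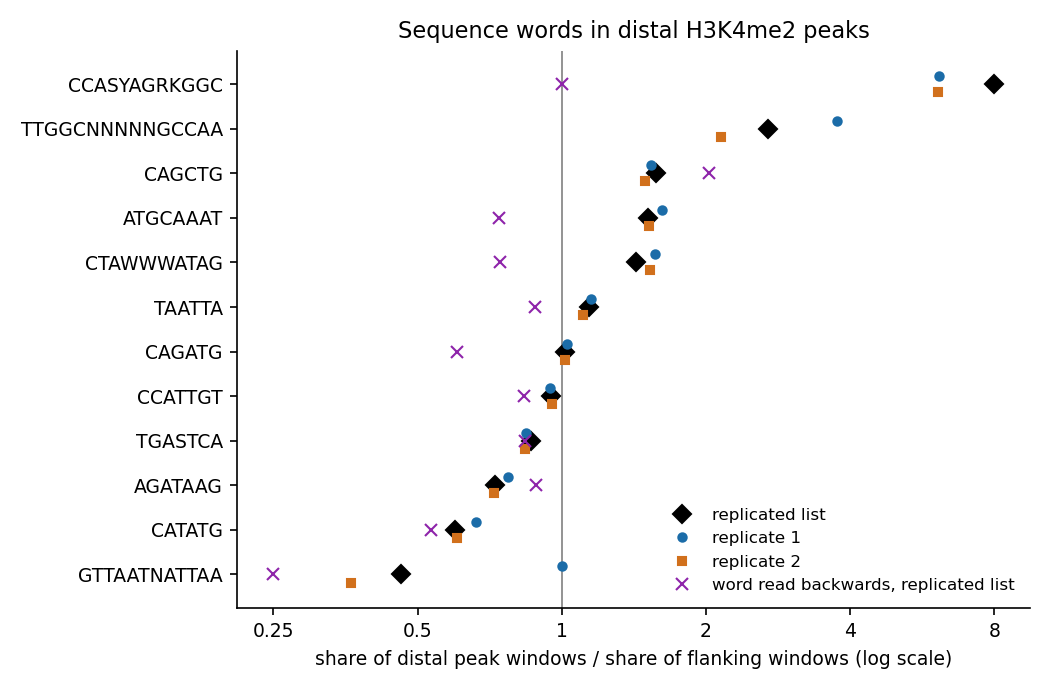
Share of distal peak windows with a sequence word over the share of flanking windows (horizontal axis, log scale) for the 12 words (vertical axis), with diamonds for the replicated list, circles and squares for replicates 1 and 2 and crosses for the word read backwards. The CTCF word CCASYAGRKGGC stood at 7.98 in the replicated list; TAATTA, at 1.14 there, turned to 0.868 with peaks at or above the median signal value.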

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

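The test of −log10 p at like signal values was chosen after the result was seen; the other tests in this part were set before it. The replicated list held 14 peaks on unlocalized or unplaced scaffolds, sequence outside the assembled chromosomes that no comparison used: 5 on X_GL456233_random with a largest signal value of 16.9, 4 on 4_GL456216_random, 2 on Un_JH584304 and 3 on other scaffolds. Each replicate's own list had 15 such peaks. They are given as values only. The design has 1 group and names no biological difference to set against the technical explanations, so no biological explanation by group was tested; a mixture of cell types is counted here among the technical ones.

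All 8 neural lists had broader H3K4me2 than lists matched on the gene's CpG ratio. Matching instead on the number of CpGs within 5 kb (CpG content beyond the start window) left 8 lists past the threshold, at 1.89 to 2.44 times the matched medians. Matching on the number of annotated protein-coding starts within 5 kb (more annotated starts near the gene) left 8 as well, at 2.43 to 4.85 times. Neither alone accounts for the pattern, and expression, which was not measured, stays open.

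Replicate 1 had 13025 peaks that touched none of replicate 2. Only 0.132% of its peaks at or above the median signal value were unshared, consistent with weak peaks near the calling threshold. In pairs with signal values within 10% of each other, −log10 p was a median of 1.43 times larger in replicate 1 (10% to 90% range 1.22 to 1.62). More significant calls at the same signal, as deeper sequencing could give, therefore remain a candidate explanation, but depth was not given. The pairing took signal values of both replicates' lists as comparable, which was not shown. The role of the further parent file of replicate 1's list was also not stated. For a different share of other cell types, 6 members of the 9 lists of blood, vessels, choroid plexus and other organs (myeloid, endothelium, choroid plexus, erythroid, liver, muscle, gut with pancreas and kidney, limb and germline) were marked in replicate 1 alone and 1 in replicate 2 alone, a difference of 5, too few to decide.

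The Hox genes were marked less often than lists matched on CpG ratio. Against lists matched on the GC content of the start window the difference was -41.0 percentage points, and against lists matched on its repeat content -33.3 points (permutation, two-sided, adjusted p = 0.001 for each). Neither property alone accounts for it. Repression by Polycomb proteins is known at Hox clusters in forebrain, but no mark of it was measured here.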

How the results depend on the processing

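The mean in place of the median, and the replicated peaks that touch both replicates, were chosen after seeing the data; all other alternatives were set before. Of the main values, 95 alternatives stayed within the spread between replicates or within 1.5 times a count, and 25 did not. For single lists, words, genes and peaks, 1163 stayed, 129 values moved, 58 calls were gained, 24 lost and 17 turned. The cause was not tested unless given by the alternative itself. Without a replicate, covered bases ranged from 41.0 to 47.1 Mb, the promoter share from 35.9 to 43.3%, X density from 7.76 to 8.34 per Mb and lists above CpG-matched ones from 1 to 2; the breadth difference of limb, bone and epidermis ranged from -150.5 to 63.5 bp, turning without replicate 1.

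With peaks at or above the median signal value, by construction fewer, there were 19984 peaks, 34.8 Mb, a promoter share of 71.6%, X density 3.67 per Mb, 3 lists above and 2 words higher. GTTAATNATTAA gave no ratio, CAGATG turned to 0.819, TAATTA to 0.868, the matched share of astrocytes to -6.67 points and the breadth of endothelium to -158.2 bp. With promoters within 2 kb the share was 49.9%, within 5 kb 59%, and by covered bases 50.8%. An overlap of 50% of both peaks left 75.5% of replicate 2, and −log10 p gave a correlation of 0.956. Lists above were 2 with 500 bp, 2 with 2 kb, 3 with the 5' end alone, and 11, with 8 below, without CpG matching, where erythroid turned to -40 points, hindbrain to 15 points and choroid breadth to -502.5 bp.

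With only marked genes, 6 lists were narrower, while liver and germline had too few marked genes to give a value; oligodendrocyte turned to 201.5 bp, endothelium to -232.8 bp and choroid to -735 bp. With 10 kb windows endothelium turned to -123 bp, muscle to 189.1 bp and limb to 304.6 bp. With the mean, 1 list, the olfactory receptors, was below in distal peaks, at 0.0291 against 0.323 in matched lists (permutation, adjusted p = 0.00083). With peaks touching both replicates, X density was 6.53 per Mb and CAGATG 0.989. With 200 bp windows 3 words were higher and CCATTGT turned to 1.02; with 10 kb flanks GTTAATNATTAA turned to 1.2. Peaks within a list never overlapped, so leaving out merging changed nothing. Depth was not given, so its effect on the number of weak peaks was not tested.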

Other observations

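Everything in this part was chosen after the values were seen, except the first test of breadth against distal peaks, which was set before. Of 2202 microRNA genes, 244 (11.1%) touched a replicated peak. Beside Mir9-1 and Mir9-3, the third copy Mir9-2 lay under a peak of 4182 bp (5029.5 ± 1223 bp in the replicates, SD, n = 2). Mir124a-1, Mir124a-2 and Mir124a-3 lay under peaks of 7119, 4729 and 6782 bp, and Mir137 under one of 7021 bp (4584 bp in replicate 1 and 6545 bp in replicate 2). Mir92b lay under a peak of 5551 bp, Mir125a, Mir99b and Mirlet7e under one of 5516 bp, Mir132 and Mir212 under one of 2555 bp, Mir129-2 under 1974 bp, Mir128-2 under 1137 bp and Mir125b-2 under 694 bp. These microRNA genes were picked by hand from the 244, with no fixed list and no test. Of the distal peaks, 1416 (6.69%) lay within 1 kb of the start of a non-coding gene, against 1.16 ± 0.071% in random placements (SD over 100 placements), so some peaks called distal here are starts of non-coding genes.

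Among the 6556 genes in the 3 lowest deciles of CpG ratio, 422 (6.44%) were marked. The 8 broadest were Kdm6b, with 9751 ± 26.9 bp, Myt1, with 6861.5 ± 876 bp, Prrt1, with 6574.5 ± 220 bp, Gpsm3, with 5864.5 ± 356 bp, Cpeb4, with 5702 ± 32.5 bp, Masp1, with 5697 ± 509 bp, Neurod6, with 5266 ± 222 bp, and Stmn2, with 4919.5 ± 61.5 bp (SD, n = 2). Breadth counts every peak within 5 kb, and at Gpsm3 the signal value listed at the start itself was 0. Its breadth may therefore belong to neighbouring genes. Among the 6555 genes in the 3 highest deciles, 45 (0.686%) were unmarked. Of the 17 Hox genes in those deciles, 8 were unmarked in the replicated list, including Hoxa5, Hoxb5 and Hoxd11. Within 5 kb of the start, Hoxb5 had 0 bp in each replicate's own list. Hoxa5 had 247 bp in replicate 1 and 181 bp in replicate 2, and Hoxd11 had 277 and 361 bp. At Hoxd11 the peaks of both replicates lay within 1 kb of the start.

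In the oligodendrocyte list, 8 genes of early lineage cells such as Olig2 and Pdgfra had a mean breadth of 2396.7 bp and 8 myelin genes such as Mbp and Plp1 had 819.3 bp (exact permutation over 12870 splits, two-sided, p = 0.13), so the hypothesis that early lineage genes are broader than myelin genes was not decided. Across marked genes, within bins of territory length, breadth and the number of distal peaks had Spearman correlations of 0.342 in replicate 1 and 0.317 in replicate 2. Peaks 1 to 5 kb from the start entered both measures, so these values do not decide whether breadth and distal peaks go together across genes. With only peaks over 5 kb from every start, outside the breadth windows, the correlations were 0.130 and 0.114, small and just above the bound of 0.1 set for the test. Breadth and peaks beyond the breadth window may therefore go together weakly across genes, which are not independent replicates.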
